A study of Mus musculus with 4 samples.

How the data were processed

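Gene expression was measured in mouse eye tissue, named retina in the labels, from control animals and from transgenic animals with myocilin, a secreted glycoprotein, in the aqueous humor. Total RNA was hybridised to 4 one-colour Affymetrix oligonucleotide arrays, 2 for each group. The labels call the second control array a technical replicate of the first, so the control group was taken as 1 sample. Nothing in the labels says that the 2 transgenic arrays came from separate animals. The p-values of single probe sets therefore measure only the spread between these samples, which may be technical.

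The values deposited by the authors were linear signal intensities, 1 for each probe set and array, for 45101 probe sets. The software and settings that made these intensities were not given in the sources used here. The mean after trimming 2% of the probe sets at each end was 150 on every array, so the deposited intensities lay on a common level. Median signals were 49.0 and 50.3 on the control arrays and 47.1 and 49.5 on the transgenic arrays. The table carried no detection calls that were used here, and the number of arrays limits the precision of every value.

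Of the probe sets, 64 were array controls and were left out of the tests. Probe sets were named from the platform annotation: 34958 had 1 gene symbol, 932 had several and 9211 had none. No gene was named from a probe set with several symbols, and an unnamed probe set is not taken to lack a gene. No symbol changed when it was updated through its gene identifier. In all, 18193 genes had a probe set of their own and 12722 had one that was tested. The gene of the transgene itself was not analysed here. No genome build was named in the sources used here, so no positions are given.

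Intensities were used as deposited because the trimmed means differed by under 5%. They were transformed as log2(signal + 16), and changes are on this scale, which understates the change of dim probe sets. Probe sets with a mean log2 value above the 40th percentile were tested, which corresponds to a signal of about 30.0 and left 27022. Control arrays were averaged on the log2 scale. The model was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation along the intensity trend, two-sided tests, Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05 on the adjusted p. The fit had 1 residual degree of freedom and 10.3 prior degrees of freedom. The lone control sample was assumed to vary like the transgenic samples.

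Gene lists covering cell types of the eye and stress, signalling and metabolic pathways were fixed before the data were examined, together with the model, the alternatives and the rule for naming genes. Each gene was represented by its probe set with the highest mean. Lists with at least 3 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Its p-values compare the genes of a list with other genes and do not measure how the shift of a list varies between samples. The percentile of the median log2 change of a list among 10000 random lists of the same size, matched on mean level, describes these arrays only. Camera with an estimated correlation and fry, which tests whether genes move on balance one way without comparing them with other genes, were alternatives. The genes named are the 12 with the largest log2 change in each direction among probe sets with 1 symbol past the threshold and with both transgenic arrays on the same side of both control arrays. A direction with fewer was filled with the probe sets with the widest gap between the groups' arrays, given as values that did not pass. Up to 4 genes with the largest absolute change in each list and all sex-linked genes complete the rule. Marker genes named for their signal were chosen after their values were seen.

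Alternatives were quantile normalization, centring on the median, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, all 4 arrays as separate samples with and without the replicate number as a block, moderation without the trend and robust moderation, leaving out each array, the mean over the probe sets of a gene, and the other probe sets of a named gene. Camera at a preset correlation of 0.1 was added after the results were seen, because the estimated correlation and fry rest on 1 residual degree of freedom.

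The model was tested on simulated data for the comparison of transgenic with control, with 27022 probe sets of which 200 changed, in 20 runs. It called 13.7% of probe sets changed 1.5-fold, 45.4% of those changed 2-fold and 84.1% of those changed 4-fold, with the right sign for 100% of those called. Of its calls, 15.7% were unchanged probe sets, above the nominal 5%, and 6.03% when the prior degrees of freedom were known. With 1 residual degree of freedom that prior was estimated between 9.31 and 93.6 for a true value of 10.3. The simulation let control and transgenic samples vary alike and independently, which these arrays cannot check. It also gave the technical control replicates less spread than they had here, where the SD of their log2 difference was 0.30. Thus 15.7% is not the false share of these arrays, and the shares recovered may differ too. In runs with no change the median number of calls was 0.5 and the highest 45, and 2 of 20 runs gave 21 or more. The list test made 0 calls in 640 tests of unshifted lists and called a list of clock genes shifted by 0.25 in 19 of 20 runs. Genes were simulated independently of each other, so these runs do not show how often lists of genes that vary together are called.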

Results

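The series compared eye tissue of control mice with that of transgenic mice that expressed myocilin in the aqueous humor, the fluid that also reaches the back of the eye. The question stated by the labels is what a high level of this protein around the retina does to retinal gene expression. Signals of 45101 probe sets were measured on 4 arrays: 2 technical replicates of 1 control sample and 2 transgenic arrays. The transgenic arrays are taken below as 2 samples, though the labels do not say that they came from separate animals. All 4 arrays carry the label retina, and they are described below as arrays labelled retina.

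On all 4 arrays, genes of the corneal surface, the pigmented layers, connective tissue and muscle gave bright signals, while most rod and cone genes were dim. Each array had a trimmed mean signal of 150, used here as a reference level. All 5 genes of the corneal and surface epithelium list exceeded a signal of 1000. Krt12, the keratin typical of corneal epithelium, had a signal of 11206 in the control sample and 13097 ± 108 (SD, n = 2) in the transgenic samples. Of the 22 rod photoreceptor genes with a probe set, 4 exceeded 150, with mean signals of 1464 for Gnb1, 237 for Abca4, 188 for Guca1a and 158 for Guca1b. Gnat1, the rod transducin subunit, had a signal of 23.9 in control and 16.8 ± 6.26 (SD, n = 2) in transgenic samples. None of the 11 cone genes exceeded 150 (0 of 11). Among the 47 markers of bipolar, horizontal, amacrine and ganglion cells, 8 exceeded 150, among them Pax6 at 2594 and Trpm1 at 2001, genes that pigmented or surface tissues of the eye also express. Mueller glia genes, many of them shared with other tissues, exceeded 150 for 10 of 14. In the lists for pigment epithelium and melanocytes, skeletal muscle and scleral fibroblasts, 11 of 12, 9 of 10 and 7 of 7 genes did. Lens genes stayed below 150 for all 18 with a probe set. Probe sets differ in how brightly they report a transcript, so single levels are not ranked against each other.

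**Figure D1:**
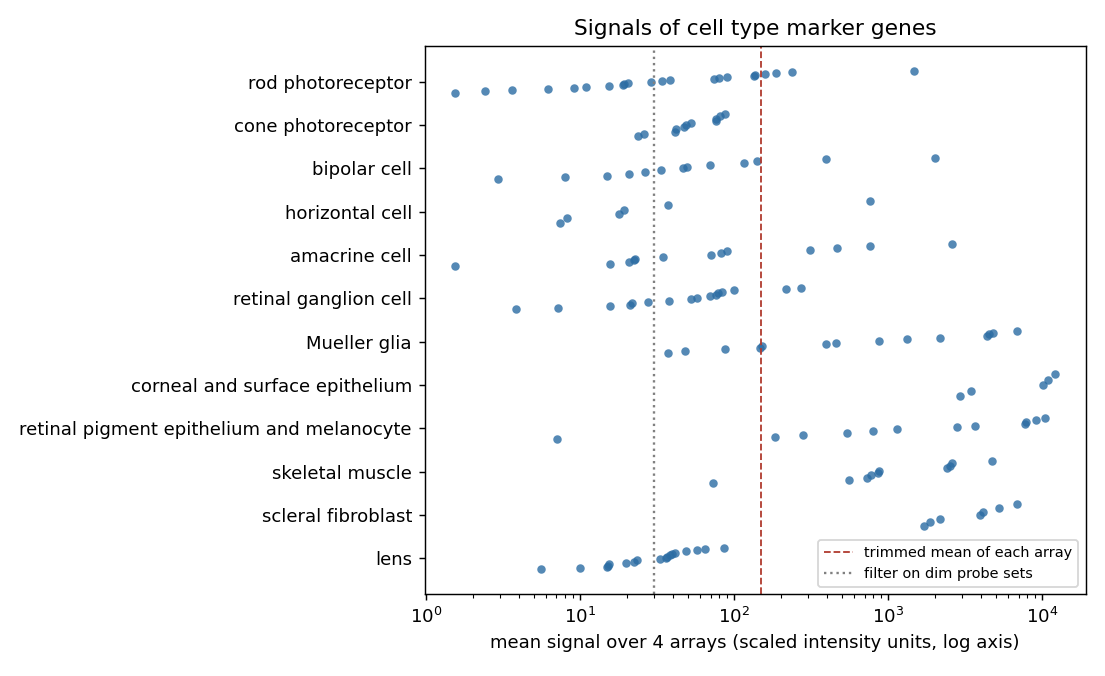
Mean signal over the 4 arrays (horizontal log axis, scaled intensity units) of each marker gene with a probe set, 1 point per gene, by cell type list, with the trimmed mean of each array at 150 as a dashed line and the filter on dim probe sets at 30.0 as a dotted line. Rod genes lie over 150 for 4 of 22 and corneal genes for 5 of 5.

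Across the 27022 probe sets tested, which are not independent replicates, the SD of the log2 difference was 0.30 between the technical control replicates and 0.32 between the transgenic samples, with Pearson correlations of 0.981 and 0.979. The ratio of these SDs was 1.07, with a bootstrap interval over probe sets from 1.05 to 1.09. With no further pair of either kind, that interval does not measure how the ratio varies between pairs of arrays. Pairs of a control and a transgenic array had SDs between 0.33 and 0.35. The 3′ to 5′ signal ratio of Actb, a measure of RNA integrity, was 1.21 and 1.19 on the control arrays and 1.22 and 1.14 on the transgenic arrays. The 5′ probe set of 18S ribosomal RNA varied within both groups, with signals of 6493 and 885 on the control arrays and 4983 and 1648 on the transgenic arrays. Poly-A control transcripts, which are added to RNA before labelling, were higher on both transgenic arrays for 18 of 27 probe sets, with a median fold of 1.18.

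Genes past the threshold with higher signals in the transgenic samples included 3 lens crystallins, visual cycle genes, muscle genes and the corneal proteoglycan gene Kera, and those with lower signals included a membrane mucin, a glucocorticoid-induced gene and a Y-linked gene. Kera, which encodes keratocan of the corneal stroma, rose by 1.54 ± 0.11 (log2, SE), from a signal of 1051 in control to 3083 ± 204 (SD, n = 2), with a limma adjusted p of 0.000286. In all, 21 probe sets passed the threshold, 15 higher and 6 lower. Of the higher ones 14 belong to 13 genes and 1, at 1.95, carries the symbols of several crystallin genes, and the lower ones belong to 5 genes. On all 21 both transgenic arrays lay on the same side of both control arrays. At an unadjusted p under 0.05 there were 1908 probe sets, 1119 higher and 789 lower. Groups of arrays did not overlap for 44.7% of the probe sets tested. Exchangeable arrays would give 33.3%, but the control arrays are technical replicates of 1 sample and so are not exchangeable with the others. The split between directions depended on the scaling, with 20 higher and 19 lower after quantile normalization and 142 higher and 35 lower after median centring. The count was 14 without the first control array, 33 without the second, and 0 in limma without the filter on dim probe sets or without the intensity trend, where 2181 and 1059 probe sets had an unadjusted p under 0.05. On simulated data, where control and transgenic samples varied alike and independently, 15.7% of calls were false, which need not hold for these arrays.

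Of the crystallin genes, which encode the main soluble proteins of the lens, 3 passed the threshold, with changes whose size depended on the pseudocount. Cryaa rose by 2.00 ± 0.29 (log2, SE; adjusted p = 0.0324), Cryba1 by 1.96 ± 0.25 (adjusted p = 0.0151) and Crygb by 1.84 ± 0.28 (adjusted p = 0.0406). Their mean control signals of 13.6, 25.9 and 19.2 lay under the filter level of 30.0, and Cryaa was at 9.47 and 17.7 on the control arrays and at 102 and 100.4 on the transgenic arrays. Over all settings the change ran from 1.09 to 2.87 for Cryaa, from 1.22 to 2.48 for Cryba1 and from 1.06 to 2.48 for Crygb, against 1.47 to 1.61 for Kera, so these genes are not ranked by size. Crybb2 at 1.03 (adjusted p = 0.488) and Crybb1 at 0.59 (0.787) did not pass, and the signal of Crygn was lower on both transgenic arrays, at 14.5 in control and 5.50 in transgenic samples. Rpe65, the retinoid isomerase of the visual cycle, rose by 1.24 ± 0.13 (adjusted p = 0.00581), from 317 to 768 ± 45.2 (SD, n = 2). Rgr, a retinal G protein-coupled receptor of the pigment epithelium, rose by 1.06 ± 0.12 (adjusted p = 0.00699), from 507 to 1075 ± 10.2. Among muscle genes, Sln, a regulator of the sarcoplasmic calcium pump, rose by 1.27 ± 0.14, Mb, which encodes myoglobin, by 1.06 ± 0.11, Myl1, a myosin light chain gene, by 1.00 ± 0.09 and Smpx by 0.89 ± 0.12, with adjusted p between 0.00341 and 0.0232. Pon1, which encodes paraoxonase, rose by 1.13 ± 0.16 (adjusted p = 0.0324). Tpm3, a tropomyosin gene, rose by 1.00 ± 0.14 (adjusted p = 0.0275) on the named probe set and by 0.94 on a second, while its other 3 tested probe sets stood at 0.06, 0.04 and, on the brightest with a control signal of 2313, −0.23.

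Genes past the threshold with lower signals in the transgenic samples came from different functions. Eif2s3y, a translation factor gene on the Y chromosome, fell by 1.15 ± 0.17 on the log2 scale (adjusted p = 0.0372), from 367 to 157 ± 4.60 (SD, n = 2). Muc4, a membrane mucin of surface epithelia, fell by 1.04 ± 0.14 (adjusted p = 0.0263), from 987 to 470 ± 65.3. Tsc22d3, a gene induced by glucocorticoids, fell by 1.01 ± 0.12 (adjusted p = 0.00732), from 1297 to 637 ± 8.60. Other probe sets of Tsc22d3 stood at −0.84 (adjusted p = 0.0570), at −0.44 and, on a dim probe set with a control signal of 31.7, at 0.24. Stk35, a kinase gene, fell by 0.87 ± 0.11 (adjusted p = 0.0196) and Mpzl2, an epithelial adhesion gene, fell by 0.73 ± 0.11 (adjusted p = 0.0350). Their other tested probe sets were also lower but did not pass in limma. That of Stk35 stood at −0.54 (adjusted p = 0.451). Those of Mpzl2 stood at −0.60 (0.373) and, on the brightest with a control signal of 2609, at −0.36 (0.416). The next widest gaps between the groups' arrays did not pass the test. They were Grip2 at −1.56 ± 0.45, Ddx39b at −1.35 ± 0.34, Sncb at −1.35 ± 0.34, Ankrd10 at −1.22 ± 0.40, Arv1 at −1.20 ± 0.42, Tcl1b1 at −0.93 ± 0.39 and Lepr at −0.92 ± 0.38 (log2, SE), with adjusted p between 0.324 and 0.655 and mean transgenic signals under 40. Brighter probe sets of Ddx39b stood at 0.01 and −0.06 and those of Ankrd10 at −0.04 and −0.06.

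**Figure D2:**
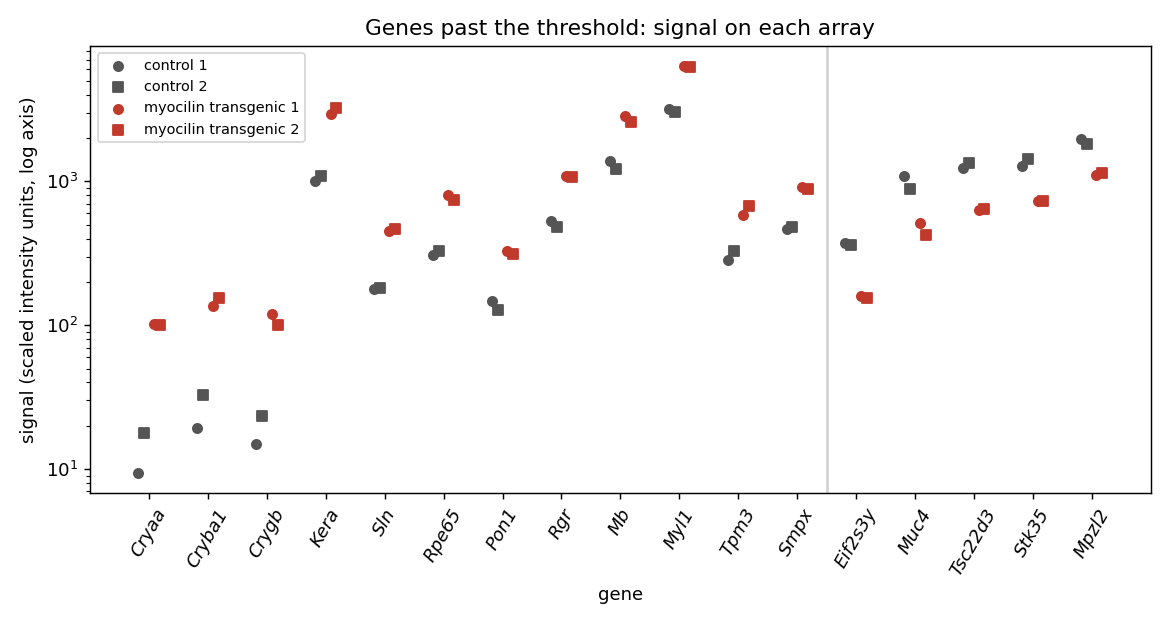
Signal of each named gene past the threshold (vertical log axis, scaled intensity units) on the 2 control arrays in gray and the 2 transgenic arrays in red, 1 point per array. Genes left of the vertical line were higher on both transgenic arrays, such as Kera at 2939 and 3227 against 1008 and 1094, and genes right of it lower.

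Camera at a preset correlation called 7 lists, those of pigmented, lens, muscle, fibroblast, red blood cell and oxidative phosphorylation genes as higher and that of the circadian clock as lower in the transgenic samples. At a preset correlation of 0.1, an alternative chosen after the results were seen, 6 of the 7 calls held and that of the shift of the circadian clock list did not (adjusted p = 0.0692). With an estimated correlation the adjusted p was 0.787 for each, and with fry between 0.124 and 0.483. These tests rest on 1 residual degree of freedom, and how readily a list passes them here was not tested. The p-values of camera at a preset correlation take genes as the units and are not evidence from replicate animals. For the retinal pigment epithelium and melanocyte list, all 11 tested genes were above 0, with a median log2 change of 0.44 (camera adjusted p = 5.57e-14). Rpe65 and Rgr passed over all probe sets tested and 7 genes passed when adjusted over the list alone, among them Lrat at 0.64 and Rdh5 at 0.62, which also serve the visual cycle. All 7 tested lens genes were above 0, with a median of 1.03 (camera adjusted p = 7.45e-09). The filter on mean signal favours genes bright in the transgenic samples here, since 6 of the 7 had control means under it. Without the filter the shift of the lens list over 18 genes was 1.03 (adjusted p = 2.64e-09), with 13 of 18 higher on both transgenic arrays and 2 lower on both. The shift of the lens list was 1.47 at a pseudocount of 1 and 0.68 at a pseudocount of 64. Cryaa, Cryba1 and Crygb passed over all probe sets and 5 genes adjusted over the list alone. The lens median also differed by 0.34 between the 2 control arrays. Of 10 skeletal muscle genes, 9 were above 0 with a median of 0.31 (camera adjusted p = 4.02e-08). Myl1 and Mylpf, another myosin light chain gene at 0.87 ± 0.10, passed over all probe sets and 5 genes adjusted over the list alone, including Myh2 at 0.48.

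For scleral fibroblast genes, the median was 0.23 (camera adjusted p = 4.89e-05, and 0.00172 at a correlation of 0.1), at percentile 96.4 of random lists matched on level, against 99.6 or more for the other lists called higher. In this list 0 of 7 genes passed over all probe sets in limma against 4 at an unadjusted p under 0.05, while Lum at 0.55, Dcn at 0.34 and Col3a1 at 0.28, all matrix genes, passed adjusted over the list alone. The shift of the scleral fibroblast list was 0.15 after quantile normalization. Red blood cell genes had a median of 0.66 over 3 tested genes (camera adjusted p = 0.0155, and 0.0367 at a correlation of 0.1), with Alas2, the heme synthesis gene of erythroid cells, at 0.72. Only Alas2 passed adjusted over the list alone, and the call of the shift of the red blood cell list ended at a pseudocount of 64 (median 0.34), at the 60th percentile filter (0.57) and without control replicate 1 (0.47). Of 22 oxidative phosphorylation genes, 21 were above 0, with a median of 0.20 (camera adjusted p = 2.41e-09, and 0.000496 at a correlation of 0.1). None passed over all probe sets in limma against 10 at an unadjusted p under 0.05, and 3 did adjusted over the list alone, namely Cox7a2 at 0.40, Atp5c1 at 0.33 and Cox6c at 0.33. The shift of the oxidative phosphorylation list was 0.11 after quantile normalization. Poly-A control transcripts, which belong to no tissue, had a median log2 change of 0.24, close in size to those of the fibroblast and oxidative phosphorylation lists. Whether the shift of these controls bears on the lists was not tested.

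Of 16 circadian clock genes, 13 were below 0, with a median of −0.25 (camera adjusted p = 0.00183). The call did not hold at a correlation of 0.1 (adjusted p = 0.0692). Per3 stood at −0.73 ± 0.17, Per2 at −0.71 ± 0.22 and Per1 at −0.63 ± 0.22 (log2, SE), the period genes of the negative limb of the clock. None passed over all probe sets in limma against 4 at an unadjusted p under 0.05, and Per3 passed adjusted over the list alone. The shift of the circadian clock list was −0.14 without myocilin transgenic replicate 1, whose removal left no test.

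**Figure D3:**
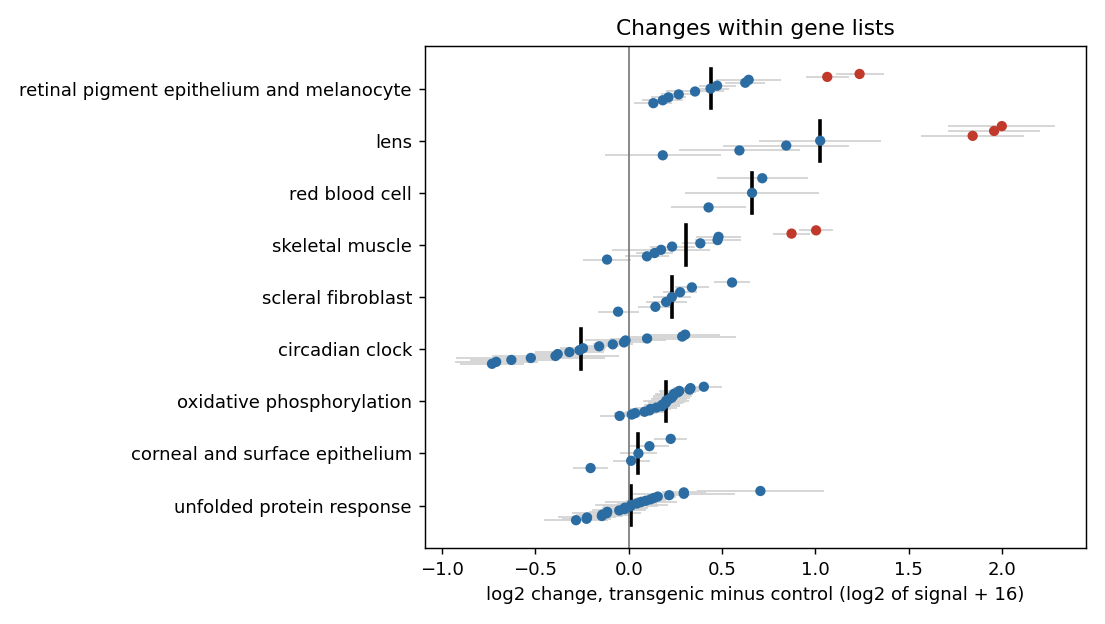
Log2 change, transgenic minus control, on the log2(signal + 16) scale (horizontal axis) of each tested gene in the 7 lists with a camera call and in the corneal and unfolded protein response lists, with gray bars for the SE, black bars for list medians and red points for genes past the threshold. Medians run from 0.20 to 1.03 in the lists shifted upwards and stand at −0.25 for the clock genes, 0.05 for corneal genes and 0.01 for the unfolded protein response.

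No retinal cell type list was called at the preset correlation. The neuron markers were mostly dim, with 11 of 22 rod genes below the filter. Median control signals were 30.8 for rod, 56.6 for cone, 46.8 for bipolar, 75.1 for amacrine and 50.6 for ganglion cell genes. These tests therefore say little about a response of retinal neurons. The medians were 0.14 for 11 rod genes (camera adjusted p = 0.258), −0.24 for 9 cone genes (0.258), −0.21 for 8 bipolar genes (0.368), −0.10 for 8 amacrine genes (0.237), −0.22 for 10 ganglion cell genes (0.302) and 0.08 for 14 Mueller glia genes (0.149), with the p adjusted over the lists in brackets. In the Mueller glia list Rlbp1, which also serves the visual cycle of the pigment epithelium, stood at 0.49 and passed adjusted over the list alone, and the list's median turned to −0.02 after quantile normalization, as the shift of the Mueller glia list. Of 16 tests of this list in other settings, 1 passed, with the replicate block (adjusted p = 0.0374). With 2 tested genes the horizontal cell list had no test and a median of −0.03. With transgenic array 1 or 2 alone, the median was 0.18 or 0.01 for rod and −0.23 or −0.09 for cone genes. For bipolar genes it was −0.15 or −0.16, for amacrine genes −0.14 or −0.02 and for ganglion cell genes −0.12 or −0.29. Synaptic vesicle and active zone genes had a median of −0.25 over 15 genes (adjusted p = 0.0756), with Snap25 at −0.56 ± 0.19. The synaptic list passed in 2 of 16 tests, after median centring (adjusted p = 0.0347) and without the intensity trend (adjusted p = 0.0363). No gene of these lists passed over all probe sets in limma, and at an unadjusted p under 0.05 there were 1 rod, 1 cone, 2 amacrine, 4 Mueller glia and 2 synaptic genes.

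Lists of damage, immune and vascular genes were not called either. Some of their medians depended on the array. With transgenic array 1 or 2 alone, the median was −0.05 or −0.22 for vascular endothelium and 0.25 or 0.06 for complement genes. Reactive gliosis genes had a median of −0.08 (camera adjusted p = 0.480), and Gfap, the glial filament gene, had signals of 39.8 in control and 36.8 ± 18.2 (SD, n = 2) in transgenic samples. In that list Cebpd at −0.62, Cd44 at −0.38 and A2m at 0.42 passed adjusted over the list alone. Microglia and macrophage genes had a median of 0.10 (0.251), where Csf1r at 0.43 passed adjusted over the list alone, complement genes 0.15 (0.109) with 9 of 9 above 0, vascular endothelium 0.02 (0.595), mural cells 0.11 (0.544), where Rgs5 at −0.40 passed adjusted over the list alone, and interferon and antigen presentation 0.08 (0.733), with camera adjusted p in brackets.

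The unfolded protein response list, which covers chaperones and sensors of secretory protein load, had a median of 0.01 over 22 genes (camera adjusted p = 0.595), with 12 above and 10 below 0 and Pdia6 at 0.30 ± 0.12. Heat shock genes had a median of 0.09 (0.444), with Hspa1a at −0.40 passing adjusted over the list alone, oxidative stress response genes −0.03 (0.999), immediate early genes 0.15 (0.237) and apoptosis genes 0.01 (0.822), where Cycs at 0.36 passed adjusted over the list alone. The medians were 0.01 for extracellular matrix (0.595), 0.16 for the olfactomedin domain family (0.483), to which myocilin belongs, 0.06 for Wnt signalling (0.595), 0.09 for neurotrophic factors and receptors (0.683) and −0.07 for cholesterol synthesis (0.237), with camera adjusted p in brackets. The cholesterol synthesis list passed in 1 of 16 tests, after quantile normalization (adjusted p = 0.0245). With transgenic array 1 or 2 alone, the median was 0.11 or 0.01 for the olfactomedin domain family and 0.12 or −0.06 for the neurotrophic list. The corneal and surface epithelium list had a median of 0.05 (0.578), which turned to −0.08 after quantile normalization, as the shift of the corneal and surface epithelium list, where it passed (adjusted p = 0.0322) in 1 of 16 tests, and the medians of the unfolded protein response and extracellular matrix lists also changed sign there. No gene of the lists in this group or of the damage, immune and vascular lists passed over all probe sets in limma, against 5 reactive gliosis, 3 microglia, 3 heat shock and at most 2 genes of any other of these lists at an unadjusted p under 0.05.

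Among sex-linked genes, Eif2s3y passed the threshold over all probe sets. The Y-linked genes Uty at −0.75 ± 0.23 and Kdm5d at −0.43 ± 0.27 and the X inactivation transcript Xist at 0.42 ± 0.13 (log2, SE) did not pass it, and Eif2s3y, Uty and Xist passed adjusted over the list alone. The signal of Uty went from 152 in control to 83.6 ± 2.35 (SD, n = 2), and that of Xist from 1374 to 1856 ± 285. Both groups thus gave signals of Xist and of Y-linked genes, as tissue of both sexes together would. Other tested probe sets stood at 0.35 and 0.61 for Xist, at −0.43, −0.73 and −0.89 for Uty and at −0.16 for Kdm5d. None of these passed over all probe sets in limma. A lower share of male tissue in the transgenic samples would go with these directions, but was not tested. The list had a median of −0.59 (camera adjusted p = 0.0569), with members that move in opposite directions by sex. It passed in 3 of 16 tests, after quantile normalization (adjusted p = 0.0449) and median centring (0.0156) and without the intensity trend (0.0232), as the shift of the sex-linked list.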

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

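The comparison of the array controls was chosen after the results were seen. A difference between groups appeared in probe sets that belong to no comparison of tissue: poly-A control transcripts, which are added to RNA before labelling, were higher on both transgenic arrays than on both control arrays for 18 of 27 probe sets, with a median log2 change of 0.24. Probe sets for mouse transcripts among the array controls were higher on both transgenic arrays for 8 of 16 and had a median of 0.19. Hybridisation controls, added later, were higher on both transgenic arrays for 0 of 18 probe sets and had a median of −0.00. They rose from transgenic array 1 to array 2, by 0.03 for BioB-5 up to 0.51 for BioB-M (log2). From control array 1 to array 2 their change ran from −0.15 to 0.24. That median therefore averages over a gap between the transgenic arrays. Several poly-A probe sets measure the same added transcript, and no test across arrays was run on any of these controls.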

How the results depend on the processing

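The other probe sets, list tests and processing settings were planned before the data were examined, except camera at a preset correlation of 0.1, chosen after the results were seen. All 21 called probe sets kept their direction in each setting that tested them. All 21 were called after quantile normalization, median centring, a pseudocount of 1 and robust moderation. The same held with arrays as separate samples and with the replicate block. At a pseudocount of 64, 20 were called, with the 60th percentile filter 17, and without the filter or the trend 0. Some calls were also lost without control replicate 1. The number of higher and lower probe sets was 20 and 19 with quantile normalization, 142 and 35 with median centring, 86 and 49 with all 4 arrays as separate samples, and 0 and 0 in limma without the filter or without the trend, where 2181 and 1059 had an unadjusted p under 0.05. With the replicate block it was 1043 and 697, but same-numbered arrays deviated together with a correlation of only 0.0955 and the numbers are not taken to pair samples. Leaving out a control replicate gave 11 to 19 higher and 3 to 14 lower. Prior degrees of freedom were 10.3, against 49.4 with median centring, 9.89 with quantile normalization, 7.62 as separate samples, 4.63 without the filter and 3.36 without the trend, so they did not follow the counts throughout, and the cause was not tested. Genes of the fixed lists past the threshold numbered 8, against 16 with median centring, 14 as separate samples, 77 with the replicate block, 0 without the filter or the trend, and 5 to 8 without a control replicate. The SD ratio of the pairs was 1.09 at a pseudocount of 1. Without either transgenic array no test was left.

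The 7 list medians, by construction unchanged under camera with an estimated correlation and under fry, were not called there: 0.44 for the shift of the retinal pigment epithelium and melanocyte list, 1.03 for the shift of the lens list, 0.66 for the shift of the red blood cell list, 0.31 for the shift of the skeletal muscle list, 0.23 for the shift of the scleral fibroblast list, −0.25 for the shift of the circadian clock list and 0.20 for the shift of the oxidative phosphorylation list. The adjusted p was 0.787 with the estimated correlation and between 0.124 and 0.483 with fry. Both rest on 1 residual degree of freedom, and how readily a list passes them here was not tested. At a preset correlation of 0.1, 6 of the 7 calls held, and the clock list (−0.25) was not called (adjusted p = 0.0692). The red blood cell list was not called at a pseudocount of 64 (0.34, adjusted p = 0.115), with the 60th percentile filter (0.57, adjusted p = 0.0790) or without control replicate 1, and its medians ran from 0.44 to 0.76 when 1 array was left out. The other ranges were 0.41 to 0.46 for the pigment list, 0.96 to 1.22 for lens, 0.27 to 0.40 for muscle, 0.19 to 0.28 for fibroblasts, −0.25 to −0.14 for the clock and 0.16 to 0.22 for oxidative phosphorylation. Another probe set reversed the direction of Tpm3 (−0.23) and a dim one that of Tsc22d3 (0.24), whose other probe sets stood at −0.84 and −0.44, and the cause was not tested. Among single genes and uncalled lists, 72 values became called, 51 lost a call, 24 moved and 2320 stayed. Dim signals limit the lens genes, with mean control signals under the filter level of 30.0 for 6 of 7 tested genes and of 44.5 for Lim2.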

Other observations

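The tests on other lists of genes, on marker counts and on uniform shifts were chosen after the results were seen, except the test of glucocorticoid-induced genes, which was written before its result was seen. In a list of conjunctival and secretory epithelium genes, 9 of 12 tested genes were below 0, with a median log2 change of −0.22 (camera p = 0.000235, and p = 0.161 with an estimated correlation on 1 residual degree of freedom). Krt19 stood at −0.45 ± 0.10, Krt8 at −0.44 ± 0.12, Krt4 at −0.36 ± 0.10 and the mucin gene Muc1 at −0.63 ± 0.17, while Krt18 at 0.29 ± 0.11 (log2, SE), Muc16 at 0.42 and Agr2 at 0.11 were above 0. None of the 12 passed over all probe sets in limma (0 of 12), 5 had an unadjusted p under 0.05 and 4 passed adjusted over the list alone.

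The 4 arrays can be split into pairs in 3 ways, which is too few for a share under 0.05. Taken as separate samples, the real split called 135 probe sets in limma and the other 2 splits 0 and 0, with 3666 probe sets against 1119 and 510 at an unadjusted p under 0.05. Both other splits put the arrays of the control sample in opposite groups.

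On all 4 arrays retinal neuron markers were dim and corneal keratins bright, although the label is retina. An effect of the transgene is argued against, since the control sample shows the pattern too, with 19 of 22 rod markers at 150 or less. A retina that had lost its rods, with no other tissue added, is argued against by the corneal and surface epithelium genes, of which 5 of 5 exceeded 1000. RNA from eye tissue other than retina may account for the pattern, as 27 of 29 pigment, muscle and scleral fibroblast genes exceeded 150, and a mix-up of samples or labels stays open. Whether retina, with or without its rods, made up part of the tissue stays open too. Of the rod markers 18.2% exceeded 150, with a median signal of 31.5 over all 22, and 1, Gnb1, exceeded 1000. But 11 of 22 lay below the filter, among them Gnat1 at 20.4, Nrl at 19.1, Prph2 at 6.17 and Pde6b at 3.61. Of the markers of other retinal neurons 8 of 47 exceeded 150. The rod markers thus give no sign that intact retina was a large part. However, no retina array was compared that shows how many would exceed 150.

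Of the muscle genes 8 of 10, of the lens genes 13 of 18 and of the visual cycle genes all 5 were higher on both transgenic arrays, while 1 muscle gene and 2 lens genes were lower on both. A larger share of skeletal muscle raises all muscle genes by a common amount if their probe sets report it equally. The variance of the changes within the muscle list was 10.8 times what their errors give (Q over its degrees of freedom). The 95th percentile for a simulated common shift was 2.49, and the 95% interval of 5 of 10 genes did not lie above 0. The simulated shift held errors only, with no difference in response between probe sets. It therefore cannot decide on a larger share of muscle, and another kind of muscle stays open too. Visual cycle and lens genes also moved unevenly, with 6.98 against 3.03 and 6.20 against 2.73. All 5 visual cycle genes were above 0 with their intervals, but they are a part of the pigment list chosen after the results were seen. In the fixed list 9 of 11 genes had an unadjusted p under 0.05 in limma. Signal ratios were 1.10 for Tyrp1, 1.14 for Pmel and 1.36 for Tyr, against 2.43 for Rpe65. Mean control signals of 6 of 7 lens genes lay under the filter level of 30.0. A larger share of pigment epithelium or of lens thus cannot be told apart from changes within those tissues. An effect of the transgene may also account for the pattern. With 1 control sample it cannot be told apart from differences of dissection or of sex composition between samples.

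Period genes, Tsc22d3 and Cebpd were lower on both transgenic arrays. Collection at another time of day predicts a rise of the opposite arm of the clock, and the mean change of Arntl, Npas2 and Clock was 0.19 ± 0.12 (log2, SE), with Clock at −0.03, a camera p of 0.232 and 0 of 3 genes past an unadjusted p of 0.05 in limma. This value is too uncertain to decide, and another time of day stays open. In the arm of the clock that holds the period genes, all 8 genes were below 0, with a median of −0.35. Camera gave p = 1.06e-06 for that arm, and p = 0.124 with an estimated correlation on 1 residual degree of freedom. Since the period genes set the pattern, that arm is no separate evidence for another time of day. Lower glucocorticoid exposure is a candidate explanation, since 10 of 11 other glucocorticoid-induced genes were below 0, with a median of −0.37. Camera gave p = 7.01e-06, and p = 0.268 with an estimated correlation on 1 residual degree of freedom. Fkbp5 stood at −0.68 ± 0.18, with signals of 209 and 336 on the technical control replicates, and Klf9 at −0.47 ± 0.11. Sgk1, with a control signal of 4820, stood at −0.01 ± 0.10, Errfi1 at −0.12 and Hif3a at 0.28. These explanations share a daily rhythm and were not separated, and an effect of the transgene stays open and untested.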
